A study of Homo sapiens with 4 samples.

How the data were processed

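Gene expression was measured in HT cells, an established line of germinal centre B-cell type diffuse large B-cell lymphoma (GCB-DLBCL). Cells carried either a non-silencing short hairpin RNA (shRNA), called control, or an shRNA against DNMT1, called shDNMT1, delivered by lentivirus. There were 2 samples per group, numbered 1 and 2 in the labels. Nothing in the sources says that they came from separate cultures, so p-values measure only the spread between these samples, which may be technical. The growth and labelling protocols also name RL cells, which were not analysed here.

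Per the labels' protocols, 200 ng of total RNA was amplified and labelled with Cy3 using a low-input kit and hybridised to single-colour Agilent arrays. The deposited scanner files hold spot intensity on a linear scale, and per the file headers the images were read with Feature Extraction 10.7.3.1 (10.7 per the submitters' processing notes). The processed intensity in these files is background-corrected but not scaled between arrays, per the file headers. A separate deposited value table holds log2 values whose processing by the authors was not given in the sources used here. Its differences between arrays followed those of quantile-normalized log2 processed intensity, with correlations across probes of 0.998 to 0.999 and slopes of 0.992 to 0.995. The log2 scale and the direction were thereby settled and the centring stays unknown. Its medians were -0.0036 and 0 for control 1 and 2, and 0.0072 and 0.00086 for shDNMT1 1 and 2.

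Each array held 58717 spots other than controls, for 50599 probes. The scanner files held no column of gene names, so RefSeq accessions were matched without versions to a table of gene symbols (assembly GRCh38.p14, used for names only). A symbol was found for 28174 probes, covering 20503 genes, and 22425 probes stayed unnamed. Of 25219 probes with an NM accession 24546 matched, and of 3962 with an NR accession 3621 matched. The design had assumed a column of gene names, and only named genes entered the main test.

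The log2 processed intensity minus the 75th percentile of its array was the main measure. That percentile was 241 and 278 in control 1 and 2, and 202 and 220 in shDNMT1 1 and 2. Spots well above background numbered 26617, 26052, 24346 and 25217 in the same order, and 0 spots were saturated. The number of arrays limits the precision. Spots with any of 3 outlier flags were treated as missing, spots of a probe were averaged, and 351 probes without a value on every array were left out. A probe was kept when well above background on both arrays of at least 1 group, which left 15347 named probes. The brightest probe over all arrays stood for a gene, giving 11645 genes, of which 2882 had more than 1 kept probe.

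Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjustment, threshold 0.05). Gene lists were tested with camera at its preset correlation of 0.01, and again with an estimated correlation and with fry. Of 38 lists fixed before the data were examined, 35 had at least 5 measured genes. DNMT1 was left out of every list. Figures were drawn with matplotlib 3.10.9. The named genes followed a rule also fixed before the data were examined. It took DNMT1, DNMT3A, DNMT3B and UHRF1, the 10 genes with the largest rise and the 10 with the largest fall among those past the threshold and above background on all 4 arrays, filled up by smallest p, genes with only a bound that passed the threshold (there were 0), and up to 4 members of each described list by smallest p. Other genes named were chosen after their values were seen, and are marked so. A list member that the rule would name is not reported here.

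The steps were tested on simulated data for the 11645 genes, with 200 genes changed. At the spread estimated from these arrays, limma called 0 of 100 genes changed by 1 log2 unit and 0 of 100 changed by 2, with 0 false calls. At an SD of 0.1 it called 100 of 100 at each size with 10 false calls. A list shifted by a fixed amount, with genes drawn independently, was called by camera at both spreads. That amount was larger than the median shifts of the DNA replication, ribosomal and epithelial lists given below. Shifts of their size were not simulated. In 20 simulated sets without any change, with genes drawn independently, 0 had a list called.

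Alternatives were normexp background correction (offset 50), quantile, median and spike-in scaling, the authors' value table, other filters and probe rules, another variance model, the replicate number as a block, and leaving out each array in turn. The files hold no mean signal column, so normexp used the median signal and median background. All arrays lay on 1 slide and were read in 1 scan, so a slide block was not run. Control arrays lay in slide column 3 and shDNMT1 arrays in column 4, so slide column and group cannot be told apart. Arrays numbered 1 lay in slide row 1 and those numbered 2 in row 2.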

Results

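Whole-transcript expression was compared between HT lymphoma cells carrying a non-silencing shRNA and cells carrying an shRNA against DNMT1, the enzyme that copies DNA methylation onto the new strand after replication. The comparison asked which genes differ in expression when DNMT1 is reduced. Each group had 2 arrays, and 11645 named genes were tested. Values are log2 signals relative to the 75th percentile of the array, as mean ± SD with n = 2 per group. Differences are shDNMT1 minus control.

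DNMT1, read by 1 probe, was 0.20 ± 0.26 in control cells and -1.04 ± 0.16 in shDNMT1 cells (SD, n = 2). The log2 difference of -1.24 (SE 0.23) left 42.2% of the control level. It was -1.17 between the arrays numbered 1, which shared a slide row, and -1.32 between those numbered 2. The direction followed the labels in both, but the difference did not pass the threshold in limma (unadjusted p = 0.0042, adjusted p = 1.00). An exact two-sided permutation test gave p = 0.333, the smallest that 2 against 2 samples allow. The de novo methyltransferases DNMT3A and DNMT3B differed by 0.25 (SE 0.19) and -0.08, and UHRF1, which recruits DNMT1 to replicated DNA, by 0.04, none past the threshold. With each array left out in turn DNMT3B lay between -0.24 and 0.071 and UHRF1 between -0.18 and 0.27. For DNMT3A 2 of 3 probes shared the sign. Its difference was -0.43 when the damaged region described next was left out, where another probe stood for the gene, and -0.08 with normexp and quantile scaling. The only kept probe of DNMT3B also lay in that region, so DNMT3B had no value with the region left out.

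**Figure D1:**
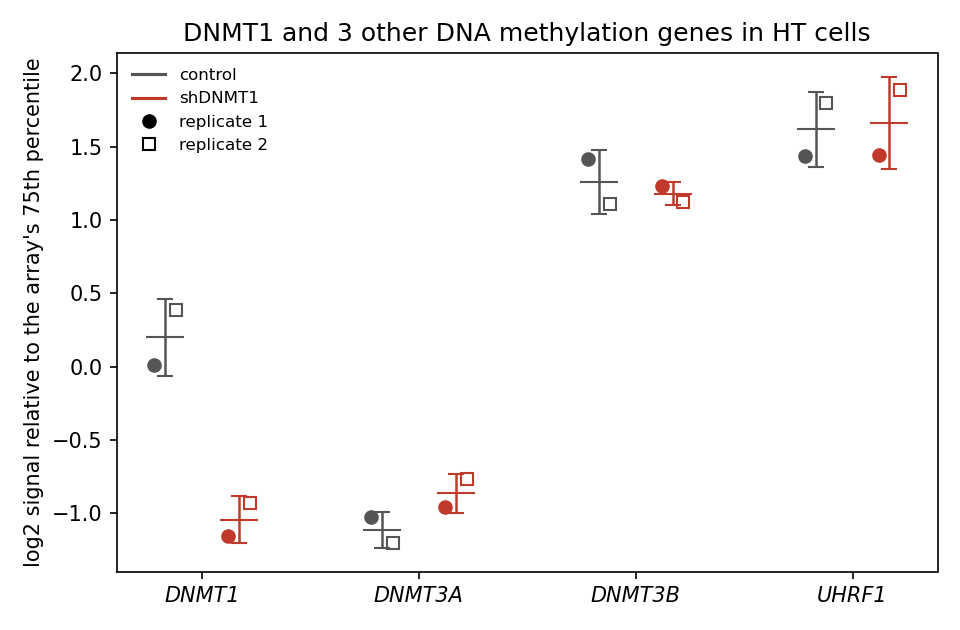
Log2 signal relative to the array's 75th percentile (vertical axis) for 4 DNA methylation genes, with 1 point per array, a horizontal bar for each group's mean and error bars of 1 SD (n = 2 per group). DNMT1 lies at 0.20 ± 0.26 in control cells and at -1.04 ± 0.16 in shDNMT1 cells, while the groups overlap or lie close for the other genes, and DNMT3A changes sign with normexp and quantile scaling.

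The array of shDNMT1 replicate 1 had a damaged area on its right-hand side, outlined in the plot of spot spread. It held 482 of that array's 514 non-uniform spots, against 0, 0 and 2 non-uniform spots on control 1, control 2 and shDNMT1 2. Probes of 2629 of the tested genes (22.6%) lay there. In 61 of these genes the probe was at least 16-fold (4 log2 units) dimmer on that array than on every other array. They include the mitotic kinase gene AURKA, at -5.26 on that array against 2.97, 3.27 and 3.13 on the others, and the pro-apoptotic gene BIK, at -5.11 against 3.96, 4.05 and 4.24. The probe of DNMT1 lay outside.

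**Figure D2:**
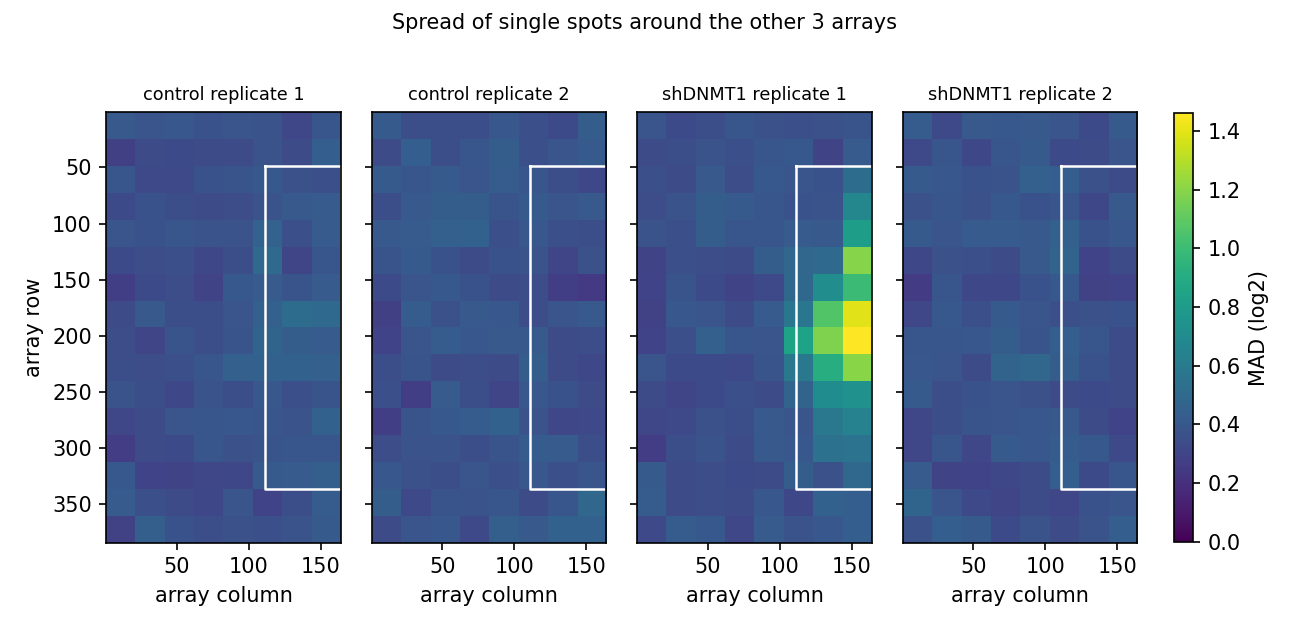
Spread of single spots around the median of the other 3 arrays (median absolute deviation, log2, colour) by array row and column, with 1 panel per array and the damaged region outlined in white. Inside the outline the spread was 0.63 on shDNMT1 replicate 1 and 0.36 to 0.42 on the other arrays.

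No single gene passed the threshold between shDNMT1 and control cells. limma called 0 genes (lowest adjusted p = 1.00), and 186 had an unadjusted p under 0.05, 128 higher and 58 lower, against 582 expected by chance. That fit kept the difference between the arrays numbered 1 and 2 in its residual. With the replicate number as a block 1035 genes had an unadjusted p under 0.05 in limma, above the 582. The low count of the main fit therefore does not show a lack of differences. Probes in the damaged region made up 34.4% of those 186. The genes with the smallest p that were higher in shDNMT1 cells were VHRT, NCAM1-AS1 and RPS7P5, which are non-coding, and CABLES1, ATOSB, SFN, HOPX, LRRC3C, LYST and BICRA. VHRT was -2.52 ± 0.29 in control and -0.26 ± 0.13 in shDNMT1 cells, a difference of 2.26 (SE 0.23, limma unadjusted p = 0.00038), and both of its probes shared the sign. SFN, which encodes 14-3-3 sigma, a p53-induced cell cycle inhibitor, was 0.19 ± 0.15 in control and 1.34 ± 0.02 in shDNMT1 cells, a difference of 1.15 (SE 0.19). CABLES1, which encodes a cyclin-dependent kinase binding protein, differed by 1.36, HOPX, a homeodomain-only cofactor, by 1.19, and ATOSB by 1.11. NCAM1-AS1 differed by 1.22, LRRC3C by 1.19, LYST, a lysosomal trafficking gene, by 0.93, and BICRA, of a SWI/SNF complex, by 1.12. RPS7P5 differed by 0.88, but its probe may also read the near-identical gene RPS7, so its source is uncertain. RPS7, looked up after the values were seen, differed by only 0.098. Between the arrays numbered 1 and 2 it differed by 0.028 and 0.17, against 0.96 and 0.80 for RPS7P5. Normexp with quantile scaling gave smaller differences for VHRT (1.28), BICRA (0.63), LRRC3C (0.75), NCAM1-AS1 (0.54), HOPX (0.47), ATOSB (0.43) and LYST (0.23), and 1.12, 1.00 and 0.92 for CABLES1, SFN and RPS7P5.

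The lower genes, besides DNMT1, were DNAJC18 (-1.01), LRRC28 (-1.05), TAF1D (-1.55), MBD4 (-0.87), ACTG1 (-0.71), FSAF1 (-0.93), NCAPD3 (-0.74), GRB14 (-0.67) and CPSF3 (-0.61), none past the threshold. MBD4 encodes a glycosylase that repairs mismatches at methylated CpG sites, TAF1D a subunit of an RNA polymerase I factor, NCAPD3 a condensin II subunit and CPSF3 the nuclease of mRNA 3' end processing. Between the arrays numbered 2, which leave the damaged array out, MBD4 differed by -0.54, TAF1D by -0.89, LRRC28 by -0.64, FSAF1 by -0.52, ACTG1 by -0.82, NCAPD3 by -0.91 and DNAJC18 by -1.15. DNAJC18 and GRB14 were -0.55 and -0.28 with normexp and quantile scaling, and -0.38 and -0.066 with normexp and the 75th percentile. Probes of 5 of the 10 higher genes (CABLES1, NCAM1-AS1, LRRC3C, LYST and BICRA) lay in the damaged region, and of 7 of the 10 lower genes, all but DNMT1, GRB14 and CPSF3. Genes at least 1.5-fold higher both between the arrays numbered 1 and between those numbered 2 numbered 88, and 32 were lower by as much in both, a count that carries no test. Leaving out control 1, control 2, shDNMT1 1 or shDNMT1 2 in turn gave 1, 0, 174 and 381 calls in limma, each resting on the assumption that the lone array varies like the other group, and the last 2 sets shared 5 genes, of which 4 had the same sign.

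Of 35 gene lists, 5 passed the threshold of camera, 1 lower and 4 higher in shDNMT1 cells, and 0 passed with an estimated correlation (lowest adjusted p = 0.96) or by fry. With an estimated correlation camera is limited to the 2 residual degrees of freedom, so it has little power there. A call lost that way does not show that members are correlated. For the DNA replication list the estimate was 0.0059, below the preset 0.01, yet the unadjusted p in camera went from 2.8e-05 to 0.046. The estimate was 0.57 for the ribosomal, 0.28 for the protocadherin, 0.18 for the epithelial and 0.050 for the HOX list. No member of the 5 lists passed over all genes or adjusted over the list alone (0 in limma in both cases), and PAX9 was the only member with an unadjusted p under 0.05. Genes of DNA replication were lower. Of 48 measured members 38 lay below 0 and 32 lay below 0 in both the arrays numbered 1 and those numbered 2. The median was -0.14, -0.14 and -0.13 over all arrays, the arrays numbered 1 and those numbered 2. MCM10, needed to activate the replicative helicase, went from -0.17 ± 0.23 to -0.58 ± 0.05, a difference of -0.42 (SE 0.21). The origin recognition gene ORC4 differed by -0.37, and RFC4 and RFC2, of the clamp loader, by -0.24 each, with the RFC2 probe in the damaged region. Normexp with quantile scaling gave MCM10 -0.23, ORC4 -0.25 and RFC4 -0.086, and a list median of -0.0545. Relative to the median of all genes the list median was -0.11 there, against -0.15 in the main setting. Spike-in scaling, which moved all genes alike, put the list median at -0.30 and left the relative value at -0.15. Without control 2 MCM10 was -0.26, ORC4 -0.25 and RFC2 -0.11, and the mean of its probes put ORC4 at -0.998. The list passed in camera (adjusted p = 0.00049, adjusted p = 0.96 with an estimated correlation). It no longer passed without control 2 (median -0.09, adjusted p = 0.33) or without shDNMT1 1 (median -0.11, adjusted p = 0.38).

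Cytosolic ribosomal protein genes, among the brightest on the array, were higher, with 44 of 49 above 0 and 41 above 0 in both arrays' comparisons. The median was 0.14, and 0.13 and 0.15 for the arrays numbered 1 and 2. RPL19 went from 8.83 ± 0.04 to 9.28 ± 0.06, a difference of 0.45 (SE 0.18), RPS18 differed by 0.33 and RPS6, in the damaged region, by 0.29, against 0.20 for RPS18 and 0.11 for RPS6 with quantile scaling. The list passed in camera (adjusted p = 8.6e-05, adjusted p = 0.96 with an estimated correlation) but depended on the scaling. Its estimated correlation of 0.57, the highest among the called lists, lies far above the preset 0.01 behind that call. That estimate leaves the difference between the sample numbers in the residual. In both groups 42 of 49 members were higher in the samples numbered 1. With the number as a block the list passed in camera at the preset correlation (adjusted p = 1.8e-05). The call was lost in camera with quantile scaling (adjusted p = 0.80), the authors' value table (0.56), both normexp settings (0.79 and 0.068) and no filter (0.62). It was also lost without control 2 (median 0.075), shDNMT1 1 (0.097) or shDNMT1 2 (0.21). Without shDNMT1 2 the list median relative to that of all genes was 0.13, as in the main setting. Relative to the median of all genes the list median was 0.13, against 0.015 with quantile scaling and 0.0071 with normexp and quantile. Spike-in scaling moved all genes alike, to a median of -0.15 and a list median of -0.02, and left that relative value at 0.13.

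Protocadherin cluster genes, cell adhesion genes read from clustered promoters, were higher with a median of 0.34, and 11 of 14 measured members lay above 0 (10 in both comparisons). PCDHGA2 went from 1.25 ± 0.06 to 1.77 ± 0.20, a difference of 0.52 (SE 0.20), and PCDHGB3, PCDHGA5 and PCDHGB2 differed by 0.50, 0.55 and 0.34, against 0.30, 0.20 and 0.16 with normexp and quantile scaling. The list median was 0.19 with normexp and quantile scaling. Relative to the median of all genes it was 0.14 there, against 0.33 in the main setting. PCDHGB3 was 0.26 without shDNMT1 2, and PCDHGA5 0.24 without control 1 and 0.85 without control 2. These genes share sequence, so signal from each other cannot be told apart with certainty. camera gave an adjusted p = 0.0012 (adjusted p = 0.96 with an estimated correlation). The call was lost in camera without filter (median 0.44, adjusted p = 0.098). There the median of all genes rose too, and the list lay 0.32 above it, against 0.33 in the main setting. Without control 2 the call was lost at a larger median (0.43). It was also lost without control 1 (median still above 0 at 0.22, adjusted p = 0.88, with camera's direction reversed) and without shDNMT1 2 (median 0.19, 0.57). Markers of other cells, epithelial and kidney (7 of 7 above 0, median 0.23) and fibroblast and endothelial (4 of 4, median 0.32), were above 0 alongside this list and the next.

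HOX and developmental regulator genes were higher with a median of 0.41, with 9 of 10 measured members, out of 53 in the list, above 0. PAX9 went from -2.50 ± 0.17 to -1.92 ± 0.11 (difference 0.58, SE 0.20), and HOXA9 and HOXA10 differed by 0.45 and 0.41. With normexp and quantile scaling PAX9 was 0.30 and the list median 0.21. Relative to the median of all genes the list median was 0.16 there, against 0.40 in the main setting. LHX2 was above background on 1 of 2 control arrays, and between the arrays numbered 2, both above background, it differed by 0.13. camera gave an adjusted p = 0.0033 (adjusted p = 0.96 with an estimated correlation). The call was lost without control 1 (median 0.32, adjusted p = 0.11), without control 2 (median still above 0 at 0.060, 0.89, with camera's direction reversed) and without shDNMT1 1 (median 0.37, 0.23). Epithelial and kidney markers, fixed as a check for other cells, were higher in all 7 measured members, with a median of 0.23. KRT18 differed by 0.30, VIM by 0.41, KRT7 by 0.23 and MUC1 by 0.51. VIM was the brightest member in control cells, at 3.97, so its reading as a marker of other cells is uncertain. The VIM difference was 0.77 between the arrays numbered 1, which include the damaged array, and 0.059 between those numbered 2. The VIM probe itself lay outside the damaged region. KRT7 was 0.11 without control 1 and 0.35 without control 2. MUC1 was -0.11 without control 2, 1.12 without control 1, 0.074 without shDNMT1 1 and 0.16 with normexp and quantile scaling. The list passed in camera (adjusted p = 0.036, adjusted p = 0.96 with an estimated correlation), and the call was lost without filter (median 0.50, adjusted p = 0.099), without control 2 (median 0.079, 0.63), without shDNMT1 1 (median 0.091, 0.73) and, at the same median, with unnamed transcripts tested too (0.096). The median was 0.35 without control 1 and 0.35 without shDNMT1 2. Fibroblast and endothelial markers, fixed for the same check, had 4 of 21 members measured, fewer than the 5 needed for a test. All lay above 0, with a median of 0.32 (0.50 and 0.21 between the arrays numbered 1 and 2). CLDN5, whose probe lay in the damaged region, differed by 0.54. Without filter, with probes not above background included, all 21 entered and the list passed higher in camera (median 0.51 against 0.12 over all genes, adjusted p = 0.00030, adjusted p = 0.62 with an estimated correlation).

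**Figure D3:**
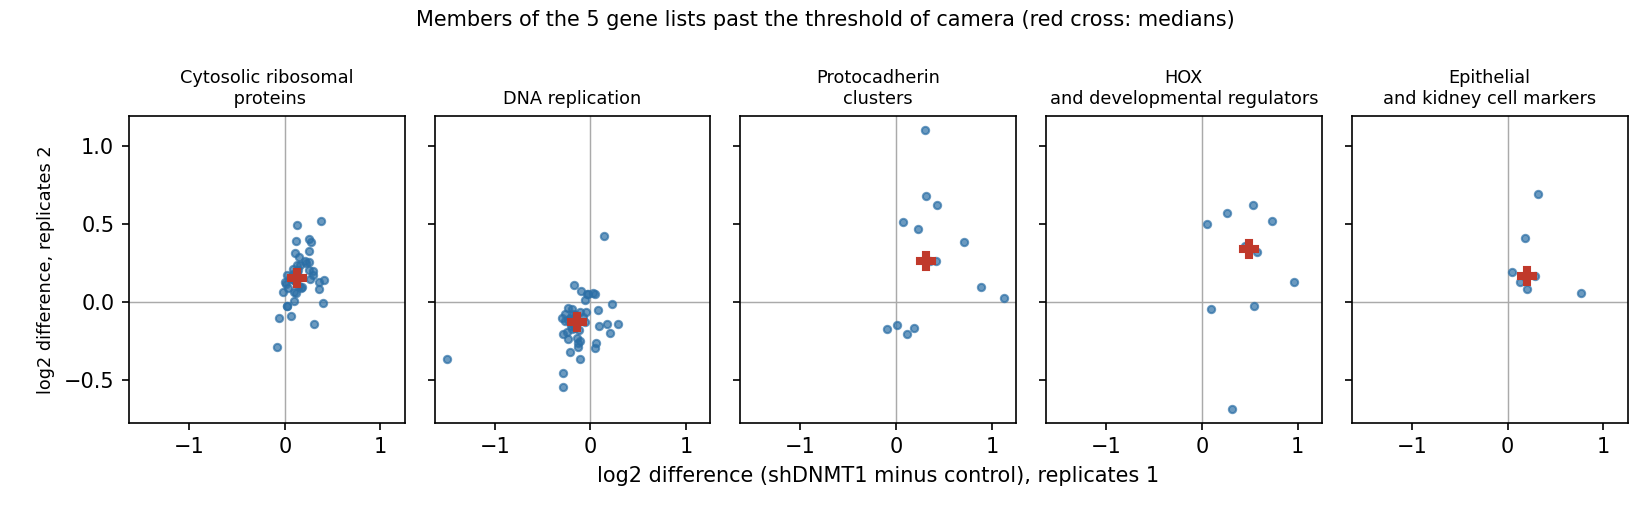
Log2 difference, shDNMT1 minus control, of each member of the 5 lists that passed in camera, between the arrays numbered 1 (horizontal axis) and those numbered 2 (vertical axis), with 1 blue point per gene and a red cross at the list's medians. Most members of the DNA replication list lie below 0 in both (32 of 48) and most ribosomal protein genes above 0 in both (41 of 49), while spike-in scaling, which moved all genes alike, put the ribosomal median at -0.02 and left it 0.13 above the median of all genes.

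The other 30 tested lists did not pass in the main test. Among genes that loss of DNA methylation is known to release, few were measured, that is, kept by the filter on background. Of 63 cancer-testis genes 48 entered without the filter and 8 with it. Probes of the rest of the 48 were not above background on both arrays of either group. Of the 8 measured, 7 lay above 0 with a median of 0.15 (camera adjusted p = 0.26). MAGEA6 differed by 0.0069 between the arrays numbered 1 and 0.76 between those numbered 2. HORMAD1 and TEX101 were above background on 1 of 2 control arrays and SSX3 on 1 of 2 shDNMT1 arrays, and between the arrays numbered 2, all above background, they differed by 0.20, 0.48 and -0.23. The cancer-testis list passed higher in 3 of 20 other settings, namely normexp with the 75th percentile (median 0.28, adjusted p = 0.0049), no filter (0.49, 0.0097) and without shDNMT1 1 (0.50, 0.00010). In the same settings it did not pass with an estimated correlation (adjusted p = 0.70, 0.62 and 0.96), and its median over the 20 ran from -0.015 to 0.50. Genes often silenced by methylation in lymphoma had a median of 0.08 over 12 members (adjusted p = 0.92), imprinted genes 0.04 over 17 (0.65). Of 34 interferon-stimulated genes 24 lay above 0, with a median of 0.09 (0.26). OAS2, an antiviral sensor whose probe lay in the damaged region, differed by 0.95 (SE 0.22), and LGALS3BP differed by 0.63. CD24, a B-cell surface gene, differed by 1.37 (SE 0.40). The p53 target list, in which SFN stood at 1.15, had a median of -0.01 over 23 members (0.94). Mitosis genes had a median of -0.04 and a mean of -0.14, a mean set by AURKA on the damaged array (adjusted p = 0.10). The mitosis list passed lower in 4 of 21 other settings, with a median of -0.11 and an adjusted p of 1.7e-05 with normexp and the 75th percentile (adjusted p = 0.70 with an estimated correlation there, and 0.62 to 0.96 over the 4). Its median over the 21 ran from -0.20, with spike-in scaling, to 0.021. Oxidative phosphorylation genes had a median of -0.04 over 43 members (adjusted p = 0.093) and passed lower in 9 of 21 other settings, in none of them with an estimated correlation (adjusted p = 0.62 to 0.99). Replication-dependent histone genes had a median of 0.13, 32 of 38 above 0 (adjusted p = 0.44), with 0.04 between the arrays numbered 1 and 0.22 between those numbered 2. With the sample number, which is also the slide row, as a block they passed higher (camera adjusted p = 0.0098, adjusted p = 0.95 with an estimated correlation). Their median turned with the array left out, to 0.69 without control 1, -0.42 without control 2, -0.32 without shDNMT1 1 and 0.61 without shDNMT1 2. Each of these fits unbalances the sample numbers. Numbers 1 and 2 differed for these genes by a median of 1.12 between the controls and 0.90 between the shDNMT1 samples. Germinal centre genes had a median of -0.07 over 26 members (0.61). In 11 of these 30 lists the median, the mean and camera's direction differed in sign, among them the lists of DNA methylation machinery, apoptosis, p53 targets and B-cell receptor signalling. Retinoic acid genes (3 measured) and mitochondrially encoded genes (0) were too few to test.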

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

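Transcripts without a gene name took no part in the gene test. Of their probes, which lie outside the main comparison, 13 were above background on both shDNMT1 arrays and on neither control array. The reverse count, above background in both control arrays only, was 193. Between the arrays numbered 1 and those numbered 2 the counts were 165 and 75, and in the crossed split of the arrays (control 1 and shDNMT1 2 against control 2 and shDNMT1 1) they were 72 and 9. The count of 13 lay within the range of these splits, which do not follow the shRNA, and so does not stand out. The reverse count of 193 lay above every count of those splits. Of named probes, 3 were above background on the shDNMT1 side only, against 248 on the control side only. Between the numbers these counts were 156 and 79, and in the crossed split 68 and 18. The count of 3 thus lay below all of them and 248 above. Those 3, named after the values were seen, read GPSM1, BRSK2 and LINC01018. The shDNMT1 arrays were dimmer, with a 75th percentile of 202 and 220 against 241 and 278 in controls, and the difference in detection was not tested.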

How the results depend on the processing

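The settings without the damaged region, with array weights, with unnamed transcripts and with outlier spots kept were chosen after seeing the data. DNMT1 kept its direction, and stayed short of the threshold, in all 20 alternatives, with log2 differences of -1.43 to -0.85. Leaving out 1 array gave 0 to 381 genes changed and 0 to 381 changed at least 2-fold, and all other settings gave 0. With the replicate number as a block (replicate block) limma called 0 genes (lowest adjusted p = 0.54). Of the genes tested there, 1035 had an unadjusted p under 0.05, against 582 expected by chance. The block kept the 5 lists and added the histone list (adjusted p = 0.0098, adjusted p = 0.95 with an estimated correlation). Same-numbered arrays deviated together (correlation across genes 0.53), but with 2 pairs the numbers are not taken as pairing. Block and region together gave 0 calls, 1440 unadjusted, and a lowest adjusted p of 0.066. VHRT passed without shDNMT1 1 (adjusted p = 0.0062) and without shDNMT1 2 (0.0017), with 0.066 to 1.00 in the other settings. Of 809 alternatives for 42 other named genes, 797 kept direction and side, though not size. That count says little about stability, because settings with all arrays called no gene and some of them leave the difference unchanged. With normexp and quantile scaling LYST went from 0.93 to 0.23 and GRB14 from -0.67 to -0.28. DNMT3A reversed to -0.080 (normexp and quantile) and to -0.43 without the damaged region, alone and with the block, where another probe was used. UHRF1 was -0.12 with spike-in scaling, which moved all genes alike and left it 0.030 above their median, as in the main setting. Over the arrays left out, UHRF1 ranged from -0.18 to 0.27, DNMT3B from -0.24 to 0.071, MUC1 from -0.11 to 1.12, and the medians of the protocadherin list from 0.19 to 0.43, of the HOX list from 0.060 to 0.53, of the epithelial list from 0.079 to 0.35 and of the ribosomal list from 0.075 to 0.22. Leaving out 1 array also unbalances the sample numbers between the groups, so these ranges include the difference between numbers 1 and 2. For MUC1 that difference was 1.23 between the controls and 0.86 between the shDNMT1 samples. Other causes were not tested. The lists called numbered 8 with normexp and the 75th percentile, 8 with spike-in scaling, 8 with outlier spots kept, 0 with an estimated correlation, 0 by fry, and 2 to 7 with 1 array left out. The DNA replication list kept its call in 17 of 21 settings, the ribosomal list in 11, the HOX list in 16, and the protocadherin and epithelial lists in 15 each. These settings overlap, so the counts are not counts of independent checks. Median and spike-in scaling only shift each array, and the authors' value table follows quantile scaling. Genes near background rest on few units of signal, and without the filter the median of all genes moved to 0.12.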

Other observations

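The strongest contrast in these arrays lay between the samples numbered 1 and those numbered 2, in both groups alike. Replication-dependent histone genes, which package new DNA in S phase, were higher in the samples numbered 1, by a median log2 of 1.12 between the controls and 0.90 between the shDNMT1 samples, and 35 of 38 were higher in both. H4C6 differed by 1.99, H4C12 by 1.83 and H2BC3 by 1.66, averaged over the groups. Genes of the integrated stress response were higher too (median 0.42 over 31 genes), with CHAC1 at 2.02, DDIT3 at 1.72 and DDIT4 at 1.53. Immediate early genes were lower in the samples numbered 1 (median -0.75 over 19 genes), FOS by -5.01 and DUSP1 by -1.82, while ATF3 stood at 1.69. Heat shock genes (median -0.55, HSPA1A -1.20) and MYC and ribosome biogenesis genes (median -0.51, MYC -1.75, BOP1 -1.39) were lower as well.

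In limma with the shRNA in the same model, camera called 6 lists between the numbers, with an adjusted p of 4.1e-11 for histones, and 0 with an estimated correlation (lowest adjusted p = 0.85). This larger model leaves fewer residual degrees of freedom, so the count of 0 carries little weight. No gene passed (0 in limma, lowest adjusted p = 0.054), but 4813 had an unadjusted p under 0.05, against 1035 for the shRNA in that model. The SD across genes of the difference was 0.56 between the numbers and 0.38 between the shRNAs.

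The tests of brightness, and of the histone list between the controls, were set before their results were seen, and all other tests below after. The difference between the numbers did not come from the damaged array alone, because the histone median between the controls was 1.25 times that between the shDNMT1 samples. Brightness of the genes is argued against too, since the histone median lay at percentile 100 of 10000 random lists matched on brightness. Culture, RNA or labelling batch and position on the slide cannot be told apart, since 0 arrays have a slide row that differs from their number. From the genes that moved, a difference in growth state or handling is a candidate explanation, which no group of the design tests. Other cell cycle lists did not move with the histones. The DNA replication list had a median of -0.14, with 26 of 48 genes lower in both groups and 14 higher. The mitosis list had a median of 0.018, with 19 of 45 higher in both and 19 lower.

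For the lists that passed between shDNMT1 and control cells, brightness of the genes alone would put a list among random lists of like brightness, but the DNA replication list lay at percentile 0, the protocadherin and HOX lists at 99.96 each and the epithelial list at 99.06. For the ribosomal list brightness stays open, although its median of 0.14 lay at percentile 99.83, because the random lists had a median of 0.078 (0.039 to 0.12), their genes were dimmer by 1.08 log2 units, which the planned test had not foreseen, and quantile scaling left 0.015. Damage to shDNMT1 1 would leave the arrays numbered 2 without the DNA replication shift, but the median there was 0.939 times that between the arrays numbered 1. Signal shared between near-identical protocadherin genes may add to that list's shift, and cannot be told apart from the effect of the sample number. The estimated correlation between the list's genes was 0.2785, and the list also differed between the numbers (camera adjusted p = 0.039, adjusted p = 0.85 with an estimated correlation). With the number in the model the estimate was 0.011. Too few residual degrees of freedom remain there for it to show what the correlation came from. The shRNA, which the design names, and a difference between the cultures stay open and were not tested apart.

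The region on shDNMT1 1 was outlined from the spread on that array, so damage was tested with blocks placed anew and on spots not used to place them. With 29 of 128 blocks of each array picked for the widest spread on a random set of spots, the spread of the 9346 other spots was 1.672 times larger inside the blocks than outside on shDNMT1 1, against 1.01 to 1.05 on the other arrays, consistent with damage to part of the array. Loss of the transcripts in the cells would scatter dimmed spots over the array, but of the 42 held-out spots at least 16-fold dimmer than on every other array 95.24% lay in the picked blocks, which hold 21.6% of the spots. The spots compared carried no outlier flag, so AURKA, BIK, IKZF3 and DNAJA1 could each be taken for a loss of expression from that array alone.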
